A study of Rattus norvegicus with 214 samples.

How the data were processed

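The study measured androgen receptor (AR) binding and gene expression in pieces of the urogenital sinus of Wistar rats on the day of birth. The tissues were the ventral mesenchymal pad (VMP) and the remaining urethral tissue of females (SU, which the labels describe as smooth muscle, mesenchyme around the urethra and urethral epithelium), and the ventral prostate (VP) and dorsal or dorsolateral prostate (DP) of males. Of the 214 samples, 6 were chromatin immunoprecipitation or input libraries, 4 were tissue RNA libraries and 204 were single cells. The peak lists cover the 4 immunoprecipitated tissues, and the 2 input libraries were not analysed here. Each tissue had 1 AR library and 1 RNA library, so no comparison between tissues has replicates.

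Tissue RNA counts were read counts per Ensembl gene, deposited without normalisation, from 100 ng of total RNA per library and a TruSeq kit, per the labels' protocols. Single-cell counts were likewise deposited as read counts per gene and cell. The cells came from collagenase-dissociated tissue captured on the Fluidigm C1, with full-length cDNA, ERCC spike-in RNA and paired 100 bp reads, per the labels' protocols. The full-length cDNA protocol gives read counts, with no molecular identifiers, so counts from 1 molecule are not independent. The submitters' processing notes name Bowtie2, SAMtools, MACS2 2.0.10, HOMER, TopHat2 2.1.0, featureCounts, Trimmomatic 0.33, TopHat, Picard 1.128, HTSeq and the build Rnor_6.0, without assigning them to files. Each peak list holds peaks shared by HOMER and MACS2 and annotated with HOMER on rn6, per the file headers. The peak height in 3 of the lists is a score given by the authors, whose unit and scale are not given in the sources used here. It was used only to rank peaks within a list. The VMP list carries no heights. All peaks of a list have the same width.

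Gene symbols were taken from a RefSeq gene table of assembly GRCr8, used for names only, and from the symbols that the peak lists pair with Ensembl identifiers. Of 28064 gene identifiers, 14617 received a symbol, 13002 through RefSeq accessions and 1615 through the peak lists. Genes with a symbol held from 77.1% of VMP counts to 77.7% of SU counts. Coordinates are those of the deposited tables, on rn6. The build named in the notes and the positions were checked against each other. Between 99.7% and 99.9% of peaks lay on the chromosome of their annotated gene, and between 95.0% and 96.1% of promoter peaks lay within 2 kb of that gene's start in the count table.

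Tissue counts were scaled with TMM factors over the 4 libraries (edgeR 4.0.16, R 4.3.3). The ratio of normalised CPM (counts scaled to 1e6 per library) was given with an exact conditional binomial (Clopper-Pearson) 95% interval. A gene counted as higher or lower when it reached 5 CPM in the higher library, differed at least 2-fold and had an interval excluding equality. With 1 library per tissue there is no replicate check, and no p-value was computed. All intervals cover counting error only, not the spread between animals. A fold against a library with a count of 0 was computed against a floor of 3 counts per library and is a lower bound. Gene lists were summarised by their median log2 ratio with a pseudocount of 1 CPM, over members with a mean of at least 1 CPM in the libraries compared. The median was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries only. Many of the 28 lists share genes with one another, and sets such as the smooth muscle genes are expressed in several of the tissues.

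The tissue groups, the comparisons, the rule of size, the gene lists, the cell type markers, the rule for naming genes and most of the other settings tried were fixed before the data were examined. Named genes in a tissue comparison are the 8 highest and 8 lowest log2 ratios past the rule with at least 100 counts in the higher library, without haemoglobins and names that are only identifiers. To these come up to 4 members of each list with the largest ratios. In cells they are the 8 highest and 8 lowest by the smaller of the within-run ratios, plus list members past the rule in both runs. For peaks they are the 5 highest of each list with heights and the peaks nearest to the paracrine factor and AR target genes. Other named genes are marked as chosen after their values were seen.

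Peaks counted as shared when they overlapped by at least 1 bp. The background was 100 random placements of each list on the same chromosomes. Promoter peaks lay within 1 kb of a transcription start site (TSS) in the authors' annotation. Genes near a peak had one within 50 kb of the gene body. The AR motif content of peaks, which was planned, needs a genome sequence and was not analysed here.

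Cells formed 4 plates, VMP run 1 (49 cells), VMP run 2 (53), VP run 1 (53) and VP run 2 (49). The cell tables held 1 further column, whose header holds an error value in place of a sample name, and it was not used. The labels' protocols state that 52 VMP and 70 SU cells were captured and 52 VMP and 63 SU cells sequenced, while the tables hold 102 VMP and 102 VP cells. For VMP the stated 52 cells and the 102 of the tables disagree, and the reason is not known. The stated SU cells and the VP cells of the tables are different tissues and are only set side by side. The labels name no animal or culture for a cell, so each tissue is 1 sample, and no test or p-value was made from cells. Genes called in cells and percentiles of lists among random lists describe these plates only. All 204 cells passed the filter of at least 1000 genes detected. The 95 spike-in transcripts, 92 of them ERCC, took 8.63% of all counts (13.6% and 5.47% on the VMP plates, 16.4% and 6.26% on the VP plates) and were left out of gene totals. In 1 VP cell of run 1 they took 97.6% of the counts. Counts were summed per plate and scaled to CPM of gene counts, and VP over VMP ratios were taken within each run number. The labels do not tie a VMP and a VP plate of 1 number to the same day, litter or batch. A gene was called when both within-run ratios were at least 2-fold the same way and 1 side reached 20 CPM in both runs. No doublet caller was run.

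Cells were clustered with scikit-learn 1.9.0 on 10 principal components of 1000 variable genes, by Ward agglomerative clustering with 2 to 8 clusters, of which the number with the largest silhouette width was kept. Several Ward clusterings were tried, with another gene filter, with fewer genes, with run or plate means removed and with marker genes alone. The last divided cells by their level of smooth muscle genes. The setting used was chosen after these had been seen. Genes entered when they were above 50 CPM in at least 3 cells and above a mean of 20 CPM, on the log2 scale after adding 10 CPM, without mitochondrial and Y-linked genes. Clusters were left unnamed. Detection was counted as at least 1 count in a cell, and also after thinning each cell to 200000 counts, which left out 1 VP cell of run 1. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. DESeq2 1.42.0 gave alternative size factors. Alternatives varied the low-count filter, the fold, the pseudocount, the peak overlap and the distances, left out each capture run, and left out groups of cells. Leaving out cells with markers of other types or of the smaller cluster, keeping only peaks away from a TSS, and recounting genes shared by the ventral comparisons were added after the data had been seen.

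The steps were tested on simulated data. Poisson counts were drawn around the mean of the libraries or plate sums compared, with 200 genes changed by known folds. Such counts hold counting error only. The shares below therefore check the steps and do not cover spread between animals, cells or runs. Of genes changed 3-fold or more, 100% were called in each of the 4 tissue comparisons. The 95% intervals held the true ratio for between 95.03% and 95.5% of unchanged genes. At exactly 2-fold, 73.9% were called for VMP over SU, 44.4% for VP over DP, 42.9% for VP over VMP and 32.5% for DP over SU. None changed 1.5-fold was called. Of 100 unchanged random lists per comparison, between 1% and 4% fell outside the central 95% of matched lists, and all lists shifted by 1.41-fold did. For the cell sums, 100% of genes changed 3-fold and 13.3% of those changed 2-fold were called.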

Results

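Tissue RNA was sequenced from 1 library each of VMP, SU, VP and DP, with 20940475, 24721403, 22325019 and 26499858 counts on genes and between 24480 and 25299 genes detected. AR-bound regions came as 1 list per tissue. Single cells were measured from VMP and VP in 2 capture runs each. The series set out to relate AR binding to the transcripts of mesenchymal subsets during prostate development. The comparisons below therefore set the ventral tissue of each sex against the other tissue taken from it, SU in females and DP in males. They also set male against female tissue, VP against VMP and DP against SU. SU is remaining urethral tissue and DP is dorsal or dorsolateral prostate, so SU and DP are not matching positions. No tissue library has a replicate, and every interval covers counting error only.

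The sex labels of the tissue libraries were checked first with the Y-linked genes Ddx3y, an RNA helicase, and Eif2s3y, a translation factor. Ddx3y had 5701 counts in VP and 6122 in DP, against 30 in VMP and 26 in SU. Eif2s3y had 4060 and 3586 counts in the male libraries and 11 and 16 in the female ones. Summed over the 19 Y-linked genes of the table, the level was 716 CPM in VP and 661 CPM in DP, and 10.2 and 16.2 CPM in VMP and SU. Mitochondrial genes took between 2.30% and 2.68% of counts in the 4 libraries. The 10 genes with the most counts took between 6.43% and 8.39%.

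Within the female, the VMP carried more Fgf10, Rspo3, Rspo2 and Ptn transcripts than SU, and fewer of epithelial and skeletal muscle genes. Fgf10, a mesenchymal growth factor that signals to epithelial buds, stood at 249 CPM in VMP and 20.3 CPM in SU (log2 ratio 3.62). The Wnt enhancers Rspo3 (38.5 against 3.93 CPM, log2 ratio 3.29) and Rspo2 (139 against 18.5 CPM, 2.91) and the heparin-binding growth factor Ptn (817 against 194 CPM, 2.07) were higher in VMP. The myosin, actin and calponin markers of smooth muscle had a median log2 ratio of 0.80, but only 1 of 9 was past the rule. The skeletal muscle markers had -2.81, with 8 of 9 lower, and the epithelium markers -1.57, with 11 of 11 lower. Of 13125 genes reaching 5 CPM, 361 were higher in VMP and 1012 lower.

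Among single genes, the highest ratios to SU were those of Elmod1, a regulator of small GTPases, at 24.8-fold (95% interval 16.6 to 38.7), and the B-cell cytokine Tnfsf13b at 23.9-fold (19.2 to 30.1). The receptor tyrosine kinase Ret followed at 18.3-fold (15.2 to 22.3), with 88.7 CPM in VMP and 4.84 CPM in SU. Kcnmb2, a potassium channel subunit, the noncoding Linc00176, the adhesion molecule Cntn4, the bicarbonate transporter Slc4a5 and the keratin Krt26 had log2 ratios between 3.67 and 4.08. Genes of skeletal muscle led the other side. The acetylcholine receptor subunit Chrna1 was 22.2-fold lower (14.9 to 34.5), Klhl40 16.3-fold (11.1 to 25) and the cadherin Cdh15 13.1-fold (10.8 to 16). Jsrp1 of the sarcoplasmic reticulum and the transcription factor Dmrt2 were lower too, with log2 ratios of -3.65 and -3.56. Duox2, an oxidase of epithelia (-3.67), Ern2, a stress sensor of mucosal epithelium (-3.63), and complement C3 (-3.62) completed the lowest 8.

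Of the 21 measured paracrine factors of prostate mesenchyme, 5 were higher in VMP and 2 lower, with a median of 0.28 at percentile 99.9 of matched random lists. Sfrp1, a secreted Wnt inhibitor, was among the higher ones (log2 ratio 2.04). The FGF list went the other way as a whole (median -0.54, percentile 0.01), with 2 members higher and 7 lower. Fgf7 had a log2 ratio of 1.68 and the receptor Fgfr4 -3.26. The Wnt list split, with 4 members higher and 6 lower (median -0.25), among them the inhibitor Wif1 (-2.36) and Wnt10a (-2.30). The BMP and TGF-beta list had a median of -0.43, with Bmp3 higher (3.03-fold, 180 against 59.4 CPM) and the BMP antagonists Grem2 (-1.78) and Grem1 (-1.54) lower. In the hedgehog list, 4 of 10 members were lower, including Gli1 (-1.29), Hhip (-1.18) and Shh (-1.17). The Notch list (median -0.52) had 3 lower members, led by Heyl (-1.38).

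Epithelial lists were lower in VMP together with the general epithelium markers, all 11 of which were past the rule. In the prostate epithelium list 9 of 13 were lower (median -1.30), including Foxa2 (-3.13), Foxa1 (-2.09) and Tp63 (-1.95). Of 11 urothelium genes 6 were lower (median -1.15), with Elf3 at -1.73. The extracellular matrix list had a median of -0.56 at percentile 0, with 4 of 28 members lower and none higher, and elastin stood at 500 CPM in VMP and 2324 CPM in SU (-2.22). Patterning factors moved both ways, with Ebf3 (2.20) and Ebf2 (2.16) higher and Sox9 (-2.07) and Sox6 (-1.94) lower. Hoxc10 (-2.02) and Hoxb5 (4-fold lower) led 3 lower Hox genes. AR target genes had a median of -0.40 at percentile 0, with Homer2 higher (1.31) and Hpgd (-1.67), Tmprss2 (-1.47) and Steap4 (-1.31) lower. In the steroid list, Srd5a2, which makes dihydrotestosterone, was higher (1.70), as was Hsd11b2 (1.23).

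Other marker lists had smaller medians between VMP and SU. The medians were -0.55 for fibroblast, -0.63 for pericyte, 0.43 for glia, 0.64 for neuron, 0.22 for endothelium, 0.19 for erythroid and -0.03 for leukocyte markers. Cell cycle genes (median -0.06) and the mitochondrial genome (-0.14) lay within percentiles 5 to 95 of random lists, and none of their members was past the rule. Immediate early and stress genes had a median of -0.38, with Klf4 lower (-1.43). In the duct list (median -0.41), Ret was higher and Wnt4 (-1.83) and Wnt5a (-1.41) lower. The medians of the hedgehog, steroid, patterning, Hox and sex-linked lists were -0.28, 0.15, -0.35, -0.40 and 0.24.

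**Figure D1:**
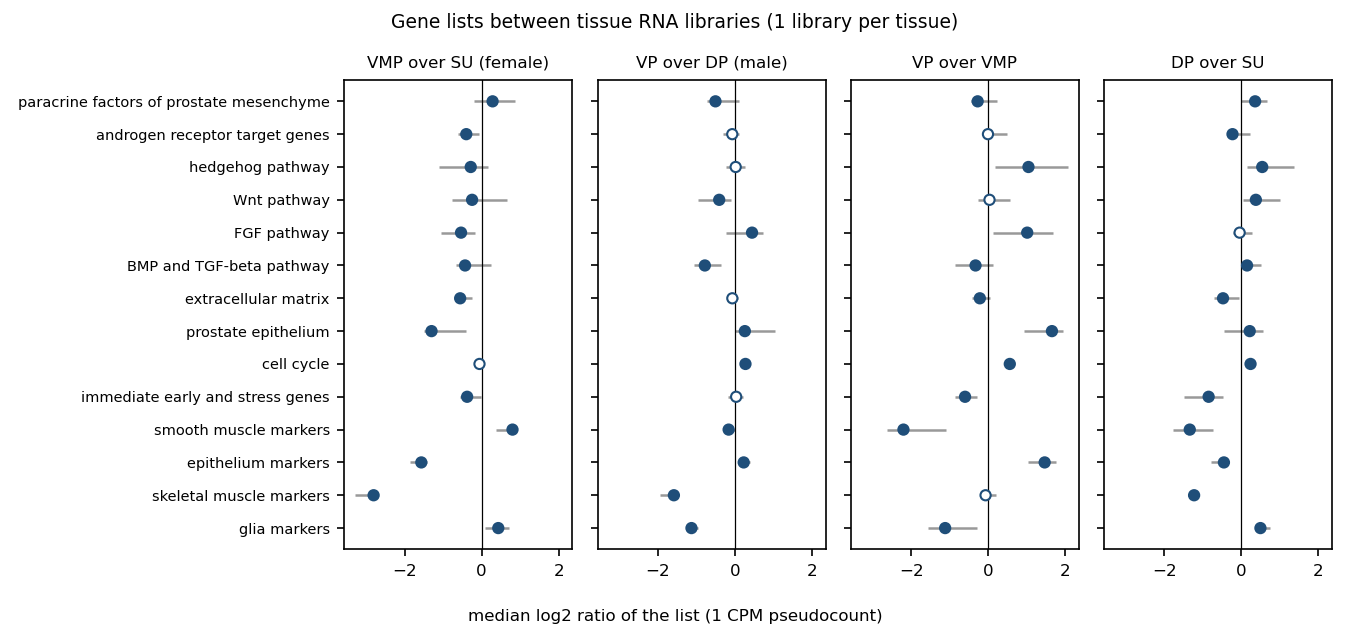
Median log2 ratio of 14 of the 28 gene lists in the 4 tissue comparisons, with a horizontal line for the order-statistic interval of the median over list members. Filled points lie outside the central 95% of 10000 matched random lists. Smooth muscle markers had medians of 0.80 for VMP over SU, -2.20 for VP over VMP and -1.34 for DP over SU.

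Within the male, DP carried more transcripts of several BMP and Wnt regulators than VP, and VP carried more Fgf9 and Fgf10. Gdf7, a BMP-family ligand, stood at 0.751 CPM in VP and 31.9 CPM in DP (42.5-fold lower in VP, 26.4 to 73.3). The BMP antagonist Grem1 was 24.1-fold lower (16.7 to 35.9), and the BMP list of 26 measured genes had 2 members higher and 10 lower (median -0.78, percentile 0), including Fst (-1.78) and Id2 (-1.65). The FGF list had a median of 0.45 at percentile 100, with an interval from -0.22 to 0.73 that holds 0. Of its 16 members 12 were not past the rule, with Fgf9 (2.02), Fgf10 (1.52, 151 against 52.8 CPM) and the feedback phosphatase Dusp6 (1.01) higher and Fgfr4 (-1.14) lower. Of 13025 genes, 213 were higher in VP and 594 lower.

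Phex, an X-linked endopeptidase of phosphate metabolism, had the highest ratio, at 33-fold (28.9 to 37.8), with 278 CPM in VP and 8.42 CPM in DP. The aldehyde oxidase Aox3 was 18.4-fold higher (15.9 to 21.5). The hindlimb transcription factors Pitx1 (11.2-fold, 8.23 to 15.6) and Tbx4 (6.72-fold, 5.92 to 7.66) were higher in VP as well. The methyltransferase Prmt8, Linc00176, the chemerin receptor Cmklr1 and the cytotoxic granule gene Nkg7 had log2 ratios between 2.43 and 2.85. Among the lowest, Sall1, a zinc finger factor of kidney development, was 37.9-fold lower (29.3 to 49.95), with 98.8 CPM in DP. The adaptor Dok6 (-5.14), the kidney cadherin Cdh16 (-4.94), chondrolectin Chodl (-4.84), the protease Tll1 (-4.83) and the adhesion molecule Cntn3 (-4.44) were lower too.

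Paracrine factors had a median of -0.50 at percentile 0 in VP, with Wnt5a (-2.47), the chemokine Cxcl12 (-1.81) and Inhba (-1.34) lower and 2 members higher, among them Fgf10. In the Wnt list 7 of 23 members were lower and 1 higher (median -0.41), including Dkk2 (-2.42), Wnt16 (-2.31) and Notum (-1.82). Notch genes Jag1 (-1.12), Hey1 (-1.08) and Dll1 (-1.08) were lower, while the list's median was -0.06. No hedgehog gene was past the rule (median 0.02), and neither was any Hox gene (median -0.40). Patterning factors again moved both ways, with 7 higher and 6 lower, including Ebf2 (2.33), Tbx18 (-2.39) and Osr1 (-2.32). In the matrix list Lum (-1.94), Bgn (-1.36), Fbn2 (-1.22) and Fn1 (-1.04) were lower. Srd5a2 was lower in VP (-2.02, 15.5 against 62.8 CPM). AR targets had a median of -0.07, with Homer2 (1.80) and Nkx3-1 (1.12) higher and Hpgd lower (-1.52).

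Markers of other cell types also differed between VP and DP. Leukocyte markers had a median of 0.77 with 5 of 11 higher in VP, and erythroid markers 0.76 with 1 of 6. Skeletal muscle markers (-1.58, 7 of 9 lower), glia (-1.13, 5 of 6 lower) and neuron markers (-1.40, 2 of 5 lower) had negative medians. Cell cycle genes had a median of 0.28 at percentile 100, but none of the 22 was past the rule. Prostate epithelium genes had a median of 0.26, with Pitx1 and Foxa2 (1.16) higher and Gata2 lower (-1.10). Medians of the epithelium (0.23), urothelium (0.24), smooth muscle (-0.16), endothelium (-0.22), fibroblast (-0.06), pericyte (-0.57) and duct lists (-0.93) complete the markers, with steroid genes at 0.03, patterning factors at -0.25, matrix at -0.07, immediate early genes at 0.03, sex-linked genes at 0.29 and the mitochondrial genome at 0.06.

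The male VP carried fewer smooth muscle transcripts and less Esr1 than the female VMP, and more transcripts of prostate epithelium and hedgehog genes. Nkx3-1, the homeobox gene of prostate epithelium on chromosome 15 (51065316 to 51068421), stood at 66.2 CPM in VP and 0.337 CPM in VMP (log2 ratio 7.62). Esr1, the oestrogen receptor alpha, stood at 19.8 CPM in VP and 413 CPM in VMP (20.9-fold lower, 19 to 23). Of 9 smooth muscle markers 8 were lower in VP, with a median log2 ratio of -2.20 at percentile 0. Of 12978 genes, 724 were higher in VP and 606 lower.

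Apart from Ddx3y and Eif2s3y, the lymphocyte genes Il2rb (559 against 4 counts), Tbx21 (4.46) and Nkg7 were among the highest in VP. Nkg7 had 326 counts in VP and 0 in VMP, so it was at least 99.7-fold higher. Prmt8 (4.79) and Rprml (4.69) were the others. On the other side, Elmod1 was 52.9-fold lower in VP (29.3 to 107). The potassium channel Kcna4 (-4.61), Klhl1 (-4.59), the endothelial adhesion molecule Selp (-4.57), the neuropeptide receptor Nmur2 (-4.47), the RNA-binding Khdrbs2 (-4.30) and tyrosine hydroxylase Th (-4.27) followed.

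Targets and components of hedgehog signalling were higher in VP, with 5 of 10 past the rule (median 1.05, percentile 100). They included Gli1 (2.43, 132 against 24.5 CPM), Hhip (2.23), Ptch2 (2.20) and Shh (1.89). In the FGF list 9 of 16 were higher (median 1.02), among them the response genes Etv5 (2.36) and Etv4 (2.25) and Fgf9 (2.22), while Fgf7 was lower (-2.85). Rspo2 was 16.9-fold lower in VP (8.21 against 139 CPM), and Dkk2 (-1.74) and Wnt11 (-1.51) were lower, whereas Wnt6 was higher (2.24). The Wnt list as a whole had a median of 0.04. In the BMP list (median -0.33) Nog (-2.60) and Bmp3 (-1.93) were lower and Grem2 (2.29) and Bmp7 (2.03) higher. Notch genes also split, with Dll1 (-2.41) and Hey2 (-1.92) lower and Hes1 (1.22) and Notch1 (1.14) higher, around a median of 0.12.

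Epithelial genes were higher in VP together with the epithelium markers, of which 9 of 11 were past the rule (median 1.47). Prostate epithelium genes had a median of 1.66 with 10 of 14 higher, including Foxa2 (4.39), Edar (2.62) and Tp63 (2.51), and urothelium genes had 0.69. Cell cycle genes had a median of 0.56, with Cenpa (1.33), Plk1 (1.21), Mcm5 (1.00) and Birc5 (1.00) past the rule. The AR target Fkbp5 (1.93) and Tmprss2 (1.15) were higher, with the list near 0 as a whole (percentile 40.1). Paracrine factors had a median of -0.27, with 1 higher and 4 lower. Immediate early genes had a median of -0.60, with 4 of 18 lower, namely Fosb (-2.38), Atf3 (-2.01), Fos (-1.97) and Nr4a1 (-1.72). Medians were -1.08 for endothelium (5 of 8 lower), -1.12 for glia (3 of 6), -1.09 for neuron (3 of 6) and 0.64 for leukocyte markers (5 of 11 higher). The remaining medians were -0.21 for matrix, -0.11 for patterning factors, 0.35 for Hox genes, 0.13 for duct genes, -0.06 for steroid genes, 0.23 for the mitochondrial genome, -0.42 for fibroblast, -0.46 for pericyte, 0.34 for erythroid and -0.07 for skeletal muscle markers, and 6.79 for sex-linked genes.

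**Figure D2:**
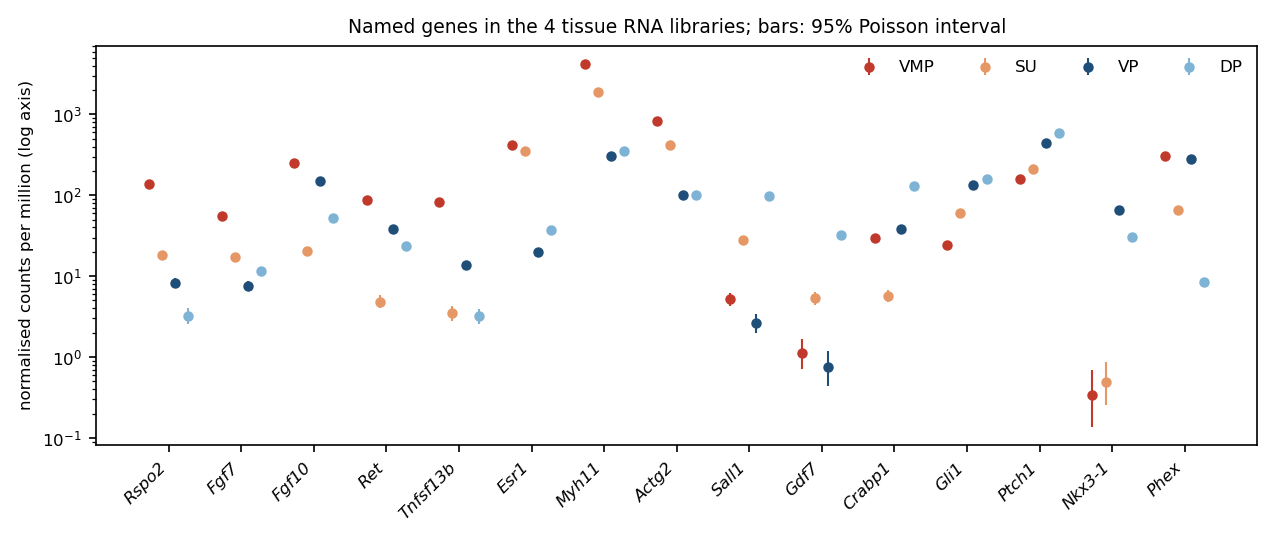
Normalised CPM of 15 genes in the 4 tissue libraries on a log axis, with 95% Poisson intervals of the count as bars; the genes were picked for display after their values were seen. Esr1 and Rspo2 lie highest in VMP and Nkx3-1 is near 66.2 CPM in VP and 30.5 CPM in DP.

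DP against SU compared the dorsal or dorsolateral prostate of the male with the remaining urethral tissue of the female. These pieces differ in tissue as well as in sex, so the differences below cannot be assigned to sex alone. Nkx3-1 (5.94, 30.5 against 0.497 CPM) was again higher and Esr1 (-3.22, 37.5 against 348 CPM) lower in the male. Smooth muscle markers were lower in DP, with 6 of 9 past the rule (median -1.34), and so were skeletal muscle markers, with 8 of 9 (median -1.23). Srd5a2 was higher in DP (3.73, 62.8 against 4.72 CPM), as were Rspo3 (3.74), Sfrp1 (2.05) and Cxcl12 (1.79). Of 13178 genes, 430 were higher in DP and 599 lower.

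Calretinin, Calb2, had 485 counts in DP and 1 in SU, a ratio of 435-fold whose interval ran from 77.7 to 17210. Rprml, likewise with 1 count in SU, had 246 counts in DP. The transcription factor Foxi1 (5.07), Cdh16 (5.04) and the retinoic acid binding protein Crabp1 (4.55, 132 against 5.63 CPM) were higher. Colec10 was 29-fold lower in DP (21.6 to 40.05) and the collagen-related Cthrc1 23.2-fold (19.8 to 27.3). Efcc1 (-4.28), Nmur2 (-4.13), myoglobin Mb (-3.76), the stress factor Atf3 (-3.76), Fibin (-3.61) and Ptprq (-3.60) were the other lowest.

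Hedgehog genes were higher in DP, with 4 of 10 past the rule (median 0.54), including Ptch2 (1.95), Ptch1 (1.46, 590 against 214 CPM) and Gli1 (1.39). The paracrine list had 6 of 21 higher and 0 lower (median 0.36). Wnt genes Notum (2.65) and Wnt16 (2.40) were higher and Rspo2 lower (-2.52), with a median of 0.38. Grem1 (1.86) and Fst (1.49) were higher and Bmp3 (-1.93) and Ltbp2 (-1.64) lower in a list with a median of 0.15. Fgf10 was higher (1.38) and Fgfr4 lower (-1.77), with a list median of -0.04. Tbx4 (-3.40) and Pitx1 (-3.49) were lower, as were Six2 (-2.31) and Pitx2 (-2.02), while Nr2f1 was higher (1.80). Elastin was lower (-2.70, 357 against 2324 CPM), with Aspn (-1.91) and Col14a1 (-1.60), in a matrix list with a median of -0.48. Immediate early genes had a median of -0.85, with 8 of 18 lower, including Fosb (-3.21), Fos (-2.35) and Nr4a1 (-1.87).

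AR targets had a median of -0.23, with Fkbp5 (1.02) higher and Abcc4 (-1.07) lower. Urothelium genes had -0.77, with Elf3 (-1.16) and Upk1b (-1.09) lower and Upk2 higher (1.85), beside epithelium markers at -0.45 and prostate epithelium genes at 0.22. Duct genes had 0.97, Hox genes 0.33, patterning factors 0.19, cell cycle genes 0.24, Notch genes -0.08, steroid genes 0.04 and the mitochondrial genome -0.03. Medians of the other marker lists were -0.68 for endothelium, -0.56 for pericyte, 0.50 for glia, 0.41 for neuron, 0.13 for leukocyte, -0.06 for fibroblast and -0.06 for erythroid markers, and 6.56 for sex-linked genes.

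The ventral tissues of both sexes were then compared through pairs that share no library, VMP over SU and VP over DP. In both pairs 60 genes were higher and 202 lower, against 3.53 and 33.7 for independent lists, and 31 and 21 genes went in opposite directions, against 11.1 and 10.8 for independent lists. Fgf10 and Linc00176 were higher on the ventral side of both sexes, and Wnt5a and skeletal muscle markers lower. Rspo2 (2.91 and 1.35) and Bmp3 (3.03-fold and 3.02-fold) were also higher in both, while Srd5a2 was higher in VMP (1.70) and lower in VP (-2.02). The genes named here were chosen after their values were seen. Across 12616 genes the ratios had a Spearman correlation of 0.167 and a Pearson correlation of 0.280, and genes are not independent replicates.

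AR peak lists differed in length and in where their peaks lay. The VMP list held 6992 peaks, SU 6460, VP 2711 and DP 14290. Promoter peaks made up 56.1% of the SU list (95% Clopper-Pearson interval 54.9 to 57.3), 36.9% of VMP (35.7 to 38), 26% of DP (25.2 to 26.7) and 19.3% of VP (17.9 to 20.9). The median distance to a TSS was 0.477 kb in SU, 17.4 kb in VMP, 34.2 kb in DP and 41.8 kb in VP. Intergenic peaks were 56.2% in VP and 34.6% in SU, and intronic ones 22.7% and 8.17%. Ranked by height within a list, the 1000 highest SU peaks were at promoters in 70.6% of cases, the 1000 highest VP peaks in 7.60% and the 1000 highest DP peaks in 4.70%.

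Most VP regions were also bound in DP. Of VP peaks 84.1% (82.7 to 85.5) overlapped a DP peak, against 33.3% for VMP and 25.4% for SU. The DP list also covered 49.1% of SU and 45.7% of VMP peaks, while 42.5% of SU peaks overlapped VMP and 39.3% of VMP peaks overlapped SU. Randomly placed peaks overlapped in at most 0.590% of cases. In VP 428 peaks (15.8%) were found in all lists and 256 (9.44%) in VP alone, while 8471 DP peaks (59.3%) were in DP alone. The DP list is the longest, and longer lists cover more of any other list. Among the 1000 highest peaks of each list, the share of VP peaks found in DP was 37.2%, and of SU peaks found in DP 2.00%.

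**Figure D3:**
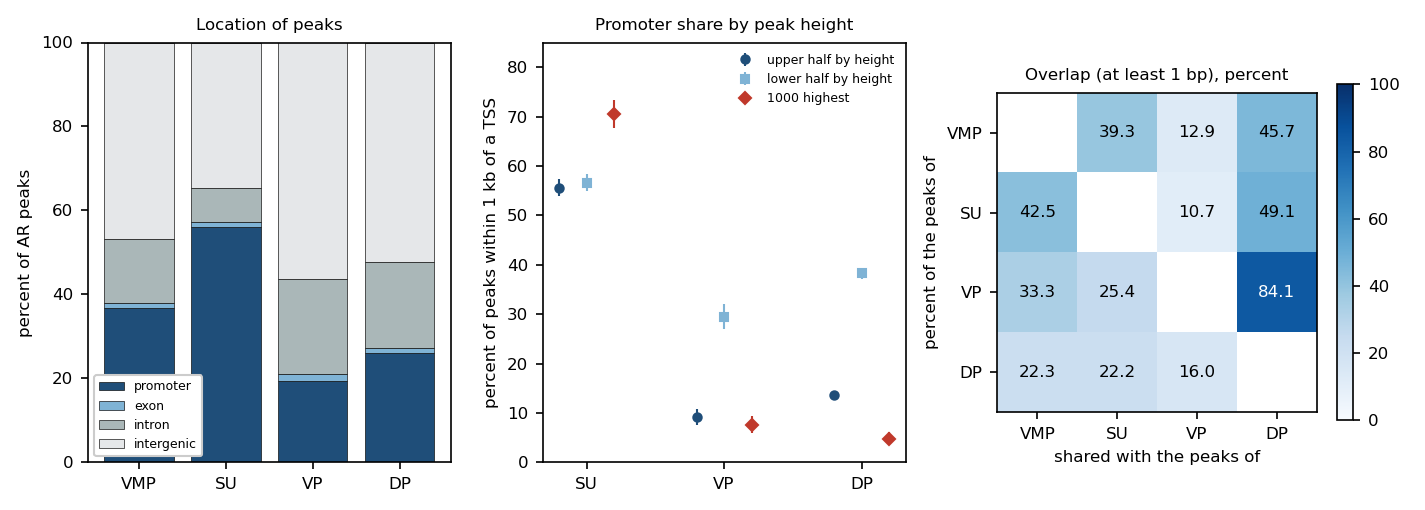
Location of AR peaks in the 4 lists as stacked percentages, promoter share by peak height in the 3 lists that carry heights with 95% Clopper-Pearson intervals, and the percentage of each list's peaks overlapped by another list. The 1000 highest SU peaks lie at 70.6% and the 1000 highest VP peaks at 7.60%, and the largest overlap is that of VP with DP at 84.1%.

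The 5 highest peaks of each list with heights mostly lay far from a TSS, and each was also in at least 1 other list. The highest SU peak (chromosome 4, 77448144 to 77448339, height 390) was intergenic, 41294 bp from the TSS of Pdia4, and was also in the VMP and DP lists. The SU peaks next in height lay nearest to Pls3, Prmt8, Trmo and the AR target Zbtb16, in whose intron a peak of height 104 stood. The highest VP peaks were intergenic near Pnpt1 (chromosome 14, 113454725 to 113454964, height 299) and Nrep (height 280), intronic in Pex11a and Atp10a, and intergenic near Hdgfl1. The Hdgfl1 region (chromosome 17, 40619830 to 40620165, 449475 bp away) held the highest DP peak, with height 536. It was followed in DP by peaks nearest to Zhx3, Klf9, Phyhip and Htr1a. The DP peak upstream of the AR target Klf9 (chromosome 1, 240831396 to 240831731, height 386) was also in the VMP and VP lists.

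The shares of fixed-list genes with nearby peaks could not be told apart from those of other genes. Of 21 paracrine factor genes, 11 had a peak within 50 kb in VMP, 9 in SU, 6 in VP and 19 in DP. Of 22 AR target genes the numbers were 12, 10, 8 and 16. Among all 13534 genes with at least 5 CPM in a tissue the shares were 56.7%, 62.6%, 23.9% and 76.2%. The list shares were 52.4%, 42.9%, 28.6% and 90.5% for paracrine factors and 54.5%, 45.5%, 36.4% and 72.7% for AR targets. Each share among all genes lay inside the binomial interval of both lists' shares. With 21 and 22 genes these intervals are wide (29.8% to 74.3% for paracrine factors in VMP), so equal shares are not shown. Fgf10 had an intronic VMP peak (chromosome 2, 51700998 to 51701229), 27633 bp from its TSS, and an intergenic DP peak 28093 bp upstream (51645220 to 51645555, height 46.7). Fkbp5 had an intronic VP peak of height 79.4 and 4 DP peaks as nearest gene. Per1, a clock gene induced by steroids, had peaks in all 4 lists within 3432 bp of its TSS. Nkx3-1 was the nearest gene of 1 DP peak, 31998 bp from its TSS.

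Expression ratios of genes near tissue-specific peaks were close to 0. Genes with a peak near them in VMP and not in SU (1503 genes) had a median log2 ratio VMP over SU of 0.08, and those with a peak in SU alone (2420 genes) -0.04. For VP over VMP the medians were 0.08 with a peak in VP alone (786 genes) and -0.01 with a peak in VMP alone (5879 genes). For DP over SU they were 0.04 and 0.01, and for VP over DP 0.01 (48 genes) and -0.02. Among matched random genes the medians for VMP over SU lay at percentiles 100 and 0.02, those for VP over VMP at 100 and 0.01, those for DP over SU at 97.47 and 6.85 and those for VP over DP at 66.4 and 1.21. Genes near neither list lay at percentiles 1.84, 98.4, 0.01 and 100 in the same order. The median of -0.01 for VP over VMP changed sign when total counts replaced the TMM factors. The median of all genes reaching 5 CPM rose alongside it, from 0.021 to 0.053.

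Single cells gave 29808935 and 134413967 gene counts from the VMP plates of runs 1 and 2 and 66100728 and 134734453 from the VP plates. The median cell had 5545 and 6357 genes detected in VMP and 4376 and 7218 in VP. Ddx3y and Eif2s3y had 0 counts in VMP cells of run 1, and in run 2 only Ddx3y was detected, in 1 of 53 VMP cells. Eif2s3y was detected in 79.2% and 100% of VP cells, and the sex-linked list had medians of 8.88 and 8.76. The 2 runs gave largely different VP over VMP ratios across the genome. Of 6040 genes with at least 20 CPM, 51.4% (50.2 to 52.7) pointed the same way in both runs, where chance gives 50%, and across genes, which are not independent replicates, the Spearman correlation between runs was 0.0685 and the Pearson correlation 0.268. Ratios of the tissue libraries correlated with those of run 1 at 0.217 and of run 2 at 0.299. Only values alike in both runs are therefore described by direction. The median gene shifted by -0.05 in run 1 and 0.41 in run 2 on the log2 scale, and with TMM scaling by 0.32 and 0.05, so list medians are read beside those of random lists.

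VP cells had far fewer smooth muscle transcripts and far less Esr1 than VMP cells in both runs. Esr1 stood at 843 and 677 CPM in VMP and at 0.0756 and 17.3 CPM in VP, and was detected in 48 of 49 and 53 of 53 VMP cells and in 9.43% and 22.4% of VP cells. Smooth muscle myosin Myh11 stood at 706 and 1500.5 CPM in VMP against 4.69 and 96.5 CPM in VP. On the VP plate of run 2 the 2 cells highest in smooth muscle markers held 82.1% of the Myh11 counts and 66.01% of the counts of all 9 markers, so summed levels there rest largely on them. Actg2, Tagln, Cnn1, Lmod1 and Acta2, which code for contractile proteins, were lower too, with log2 ratios from -9.21 to -1.93 in run 1 and from -3.28 to -2.42 in run 2. The 9 smooth muscle markers had medians of -3.80 and -3.06, at percentile 0 in both runs, where random lists had -0.01 and 0.26. In the median cell their summed level was 523 and 5242 CPM in VMP against 14.3 and 153 CPM in VP.

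The 4 list medians given by direction here (smooth muscle, hedgehog, cell cycle and mitochondrial) were picked after the values were seen, being alike in both runs. Hedgehog genes were higher in VP cells, with medians of 1.14 and 1.23 over 8 genes against -0.40 and 0.45 for random lists. The receptor Ptch2 stood at 40.8 and 34.7 CPM in VP against 0.0671 and 0.357 CPM in VMP. Ptch1 (1.03 and 1.97) and the transcription factor Gli2 (1.05 and 1.48) were past the rule in both runs. Wnt regulators were lower in VP, namely Rspo2 (-3.66 and -1.71) and Dkk2 (-7.30 and -4.18), and so were Fgf7 (-3.10 and -3.18), the receptor Fgfr2 (-8.32 and -3.37), the BMP antagonist Chrdl1 (-2.35 and -1.66), Nr2f1 (-2.09 and -1.25) and the matrix gene Lum (-1.11 and -1.69). Ptn (2.22 and 1.56), the elastic fibre gene Fbln5 (3.74 and 2.55), the AR target Acsl3 (2.49 and 2.14), Mcm5 (1.45 and 1.28) and the phosphatase Dusp1 (1.39 and 1.47) were higher. In the tissue libraries Ptch2 and Mcm5 were also past the rule as higher in VP, and Rspo2, Dkk2 and Fgf7 as lower. Ptn, Acsl3 and Dusp1 were not past it as higher there, nor Fgfr2 as lower. In cells, cell cycle genes had medians of 0.77 and 0.60 against -0.06 and 0.23 for random lists. The mitochondrial genome had -0.98 and -1.02 against 0.15 and 0.13, with 4 of its 13 genes past the rule. In the tissue libraries its median VP over VMP went the other way (0.23, percentile 98.1). The median mitochondrial share of a cell's counts was 9.84% and 25.5% on the VMP plates and 6.27% and 13.4% on the VP plates. It varied between plates of 1 tissue, so no lower expression in the VP itself is read from these medians.

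Leukocyte genes were also among the highest in VP, in a minority of cells. Rgs1, Nkg7, Ccl5 and Il2rb had between 28.4 and 99.1 CPM in each VP plate, while Nkg7 was detected in 9.43% and 18.4% of VP cells. Leukocyte markers had medians of 2.85 and 3.87, and 1 cell on each VP plate carried at least 3 of them above 50 CPM. Without the 9 cells that carried markers of leukocytes, endothelium or pericytes the median over both runs was -0.96. The tetraspanin Tspan8 was at 188 and 193 CPM in VP and at 0.0335 and 2.19 CPM in VMP. Lmcd1, the troponin Tnnc2, the carbonic anhydrase Car3, Lrrc4c, Cpne8, the GABA receptor subunit Gabrb3 and Gdap1 were the lowest in VP beside Esr1. Gdap1 came from 1 of 53 cells on the VMP plate of run 2. Endothelium markers were lower in VP in both runs (-3.61 and -0.66), but the median over both runs was 0.04 without those 9 cells.

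Several lists had medians of different sign in the 2 runs, but so did their matched random lists (from -0.65 to -0.07 in run 1 and from 0.31 to 0.50 in run 2), so no direction is read from these signs. Paracrine factors had medians of -0.31 and 0.69, immediate early genes -1.21 and 0.46, AR targets -0.35 and 0.82, BMP genes -1.02 and 0.61, Notch genes -0.89 and 1.24, steroid genes -0.56 and 0.29, patterning factors -0.24 and 0.32, pericyte markers -4.44 and 2.46 and neuron markers -3.75 and 1.71 (2 and 1 genes). FGF genes (0.39 and 1.05), matrix genes (0.16 and 0.56), fibroblast markers (0.57 and 0.38), Wnt genes (-1.06 and -0.18) and Hox genes (-0.68 and -0.90) did not. Prostate epithelium (-2.40 and 0.80) and urothelium genes (-2.40 and -0.89) rested on at most 4 genes. Erythroid (-3.69 and -0.73), glia (-1.58 and -1.04), skeletal muscle (-1.91 and -1.24) and duct genes (-1.72 and -0.32) rested on 3 to 6 genes. Fgf10 stood at 452 and 233 CPM in VMP and 501 and 305 CPM in VP, and Igf1 at 659 and 709 CPM and 778 and 838 CPM. Both were chosen after their values were seen.

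Ar was detected in most cells of both tissues, in 100% and 98.1% of VMP cells and in 69.8% (55.7 to 81.7) and 95.9% of VP cells. Its summed level was 364 and 79.1 CPM in VMP and 247 and 79.2 CPM in VP. The AR target Fkbp5 was detected in 8.16% and 24.5% of VMP cells and in 22.6% and 77.6% of VP cells, and its ratio changed sign between runs (-0.78 and 3.19). Nkx3-1 had 0 counts in all 204 cells. The upper 95% limit of the share of cells with a count was between 6.72% and 7.25% per plate, and it does not cover transcripts missed within a cell. At most 1 epithelium marker could be measured in the cell sums. Haemoglobin transcripts, which fibroblasts do not make, were present at some level in 41 of 49 and 53 of 53 VMP cells, so detection alone does not show expression.

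**Figure D4:**
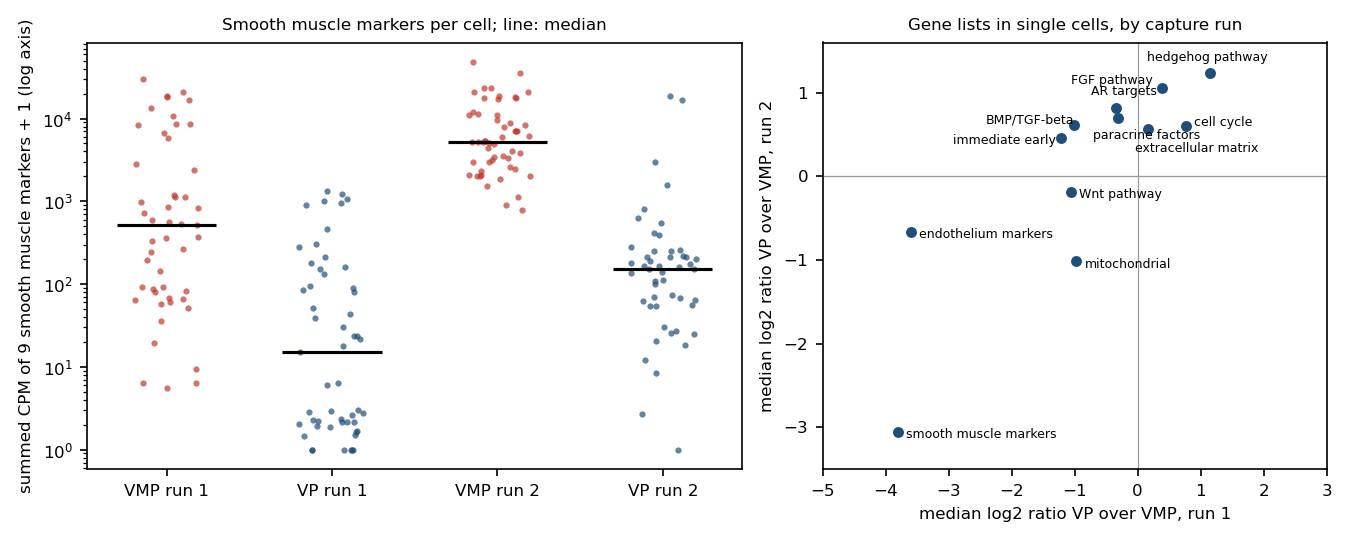
Left, summed CPM of 9 smooth muscle markers in each cell by plate, plus 1, on a log axis, with a line at the median (523 and 5242 CPM in VMP and 14.3 and 153 CPM in VP). Right, median log2 ratio VP over VMP of 12 gene lists in run 1 against run 2, where smooth muscle markers lie at -3.80 and -3.06.

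Clustering divided the cells into a larger group and a smaller one led by mitotic genes such as Top2a, Mki67, Kif11 and Aurkb. The smaller cluster held 22.5% (14.9 to 31.9) of VMP cells and 37.3% (27.9 to 47.4) of VP cells, with 8.16% and 26.4% in run 1 and 35.8% and 49% in run 2. Leading genes of this cluster belong to the cell cycle list, which itself differed between the tissues, so the shares are no separate evidence and no difference is read from them. Without these 61 cells the cell cycle median over both runs was -0.58. With 3 clusters the silhouette width dropped from 0.284 to 0.169, and the third group held cells of run 2 with 1 exception.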

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

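Of the tests in this part, those of the number of smooth muscle cells and of the share of fibroblasts were chosen after the result was seen, and that of free RNA before.

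When the ventral tissue was set against the other tissue of its sex, the medians of several gene groups differed in direction between the pairs. They lay beyond the central 95% of random lists on opposite sides. The reference was remaining urethral tissue (SU) in females and prostate (DP) in males, so these differences mix sex with unlike reference tissues. They rest on 1 library per tissue and were not tested. Taking the median log2 ratio VMP over SU minus that of VP over DP, the differences were 0.79 for paracrine factors (0.28 and -0.50), -0.98 for FGF genes (-0.54 and 0.45), -1.56 for prostate epithelium (-1.30 and 0.26), -1.39 for urothelium (-1.15 and 0.24), 0.96 for smooth muscle (0.80 and -0.16), -1.80 for epithelium (-1.57 and 0.23), 1.56 for glia (0.43 and -1.13) and 2.04 for neuron markers (0.64 and -1.40). Several rest on few genes: the interval of the median held 0 in both pairs for paracrine factors and neuron markers, and in VP over DP for FGF, prostate epithelium and urothelium genes. Of the smooth muscle markers 1 of 9 was past the rule in VMP over SU and 0 of 9 in VP over DP, where 0 of 10 urothelium genes were past it too. Among single genes past the rule in opposite directions, Foxa2, a transcription factor of epithelium, differed by -4.29 (-3.13 and 1.16), and Srd5a2, which makes dihydrotestosterone, by 3.72 (1.70 and -2.02).

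The same contrast arranged as male against female, VP over VMP minus DP over SU, is for each gene the difference above with its sign turned and not a separate observation; for lists the values differ because they are medians. It was likewise not tested. Lists on opposite sides in this arrangement had -0.63 for paracrine factors (-0.27 and 0.36), -0.48 for BMP and TGF-beta genes (-0.33 and 0.15), 1.46 for urothelium (0.69 and -0.77), 1.92 for epithelium (1.47 and -0.45) and -1.61 for glia markers (-1.12 and 0.50). The interval held 0 on both sides for paracrine and for BMP and TGF-beta genes, and 0 of 6 glia markers were past the rule in DP over SU. The receptor Ret differed by -3.49 (-1.22 and 2.27), with 88.7 CPM in VMP, 4.84 in SU, 38.1 in VP and 23.4 in DP.

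In the single-cell tables, 3 control transcripts other than ERCC carried a signal that no comparison uses. They held 187 counts in all, 147 and 16 on the VMP plates and 18 and 6 on the VP plates, and were present in 47 of 49, 14 of 53, 13 of 53 and 5 of 49 cells.

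For the smooth muscle genes that were lower in VP than in VMP, sex and tissue are biological explanations that this contrast cannot tell apart. VP is male prostate and VMP a female mesenchymal pad. Technical explanations were weighed beside them. If the VMP only held more smooth muscle cells, its lowest cells might resemble VP cells; the 10th percentile of VMP cells was 2.21 times the median VP cell in run 1 and 13.2 times in run 2, which the spread over cells left undecided. A first version of that test compared median cells (523 against 14.3 CPM and 5242 against 153 CPM) and counted against the explanation; it was replaced after these values were seen, because a tissue made mostly of such cells could shift the median as well. Free RNA of lysed cells in a suspension could add the same level to every cell, though the protocol of the tissue libraries names no dissociation. It stays open in cells. Over VMP cells of run 2 the spread of the smooth muscle sum was 2.02 times that of haemoglobin, against a bound of 2. In VMP run 1 the smooth muscle sum ran from 31.7 to 13993 CPM between the 10th and 90th percentiles, and haemoglobin from 0 to 584 CPM. Haemoglobin itself was so uneven there that run 1 decides nothing. A lower share of fibroblasts in VMP would raise all other cell types alike, but the epithelium median VMP over VP was -1.47 beside 2.20 for smooth muscle. As VP over VMP, endothelium (-1.08), glia (-1.12) and neuron markers (-1.09) were lower, like smooth muscle. Medians were -0.46 for pericyte, 0.64 for leukocyte, 0.34 for erythroid and -0.42 for fibroblast markers, each with an interval that holds 0. Epithelium thus went the other way from the endothelium, glia and neuron markers, and these types were not raised alike. These values cannot separate a lower fibroblast share from other differences in cell content, so it is left undecided.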

How the results depend on the processing

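No comparison of tissues has replicates, so the values below show dependence on settings, not on animals. Ratios of VP over VMP in cells were taken between plates with the same run number. No paired analysis was possible because the labels do not say that plates of 1 number were captured together, and the cell numbers are capture sites and not animals. With total counts or DESeq2 size factors every count of genes past the rule stayed within 1.5 times. Without a filter on low counts, at 20 CPM and at 4-fold, 4118, 711 and 330 genes were past the rule for VMP over SU (1373 before), 3035, 345 and 161 for VP over DP (807), 4040, 699 and 304 for VP over VMP (1330) and 3417, 507 and 200 for DP over SU (1029), since the rule admits more or fewer genes. Genes shared by both ventral comparisons were 212, 32 and 5 higher (60) and 474, 78 and 15 lower (202). Among genes named in the tissue comparisons 547 values stayed and 11 moved, and among gene lists 325 stayed and 11 moved, with no direction reversed.

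In cells, the share of genes alike in both runs (51.4%) was 53.1% with the mean of each cell's CPM and 56.2% at 100 CPM. The following changed with the cells or scaling used, and the cause was not tested. Hedgehog genes went to 0.89, cell cycle genes from 0.55 to -0.58 and leukocyte markers from 3.94 to -0.91 without the smaller cluster, which is itself led by cell cycle genes. With TMM factors cell cycle genes had 0.35 and the mitochondrial genome -1.19 (-1.04 before). Without cells holding markers of other types, endothelium markers reversed to 0.039 and leukocyte markers to -0.96. Leaving out each run in turn, smooth muscle markers ranged from -3.80 to -3.06, immediate early genes from -1.21 to 0.46 and neuron markers from -3.75 to 1.71. The smaller cluster ranged from 8.16% to 35.8% in VMP and from 26.4% to 49% in VP. List values in cells stayed in 188 cases, moved in 28 and reversed in 6, these included, and those of named genes stayed in 184 and moved in 32. Of the detection values 390 stayed and 234 moved, 122 with at least 5 counts and 112 after thinning, with Ar in VMP run 2 at 86.8% (98.1%) after thinning and in VP run 1 at 54.7% (69.8%) with at least 5 counts.

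Peak overlaps moved under nearly all settings, 34 of 36, and by construction fall with a stricter overlap or a shorter list. At 50% of both peaks, 31.5% of VMP peaks were shared with DP, 31.4% of SU with VMP, 31.2% of SU with DP, and of VP peaks 27.04% with VMP, 17.5% with SU and 74.1% with DP. Over 1 kb from a TSS, a setting added after the data had been seen like the exclusions of cells and the shared genes, the values were 36.6%, 40.6%, 46.5%, 26.9% and 18.6% in that order up to SU. In the higher-scoring 50% of each list, SU shared 16.7% with DP, and VP 10.3% with SU and 80.3% with DP, and among the 1000 highest peaks 2.00%, 3.30% and 37.2%. Promoters of 3 kb held 39.7% of VMP, 59.8% of SU, 22.8% of VP and 28.7% of DP peaks.

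Genes near peaks had medians so close to 0 that many moved. With total counts the median of all genes reaching 5 CPM rose too. It went from 0.033 to 0.090 for DP over SU, from 0.021 to 0.053 for VP over VMP and from -0.0046 to 0.017 for VMP over SU. The moves with total counts thus follow a shift shared by all genes. The cause of the moves with distance was not tested. For VMP over SU with a peak in SU alone the median was -0.0095 in the gene body and -0.016 with total counts. For VP over VMP it was 0.045 and -0.035 in the gene body for VP alone and VMP alone, and 0.017 (reversed) for VMP alone with total counts. For DP over SU and DP alone it was 0.055 within 10 kb, 0.053 in the gene body and 0.091 with total counts, and 0.064 for SU alone with total counts. Genes near neither list reversed for VP over DP, to -0.0086 within 10 kb and -0.011 in the gene body, and for DP over SU, to 0.012 in the gene body and 0.043 with total counts. Not run were the AR motif alternatives, which need a genome sequence, fibroblast-like cells alone, since clusters were left unnamed, 1 cluster fewer, which leaves no groups, and VMP peaks by height, since that list carries none.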

Other observations

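Of the tests in this part, that of weak promoter peaks was chosen after the result was seen, and those of list length, expression at promoters and tissue handling before.

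Several genes of the fixed lists were the nearest gene, at any distance, of AR peaks in more than 1 tissue list. Zbtb16, a transcription factor induced by steroids, was the nearest gene of 3 peaks in VMP, 2 in SU, 4 in VP and 8 in DP, with a highest DP peak of 248. The heparin-binding factor Ptn had a VMP peak 259 bp and an SU peak 19 bp from its TSS, and the VP peak, of height 100.1, lay in an intron 96848 bp away. Tbx3, a factor of limb and mammary development, was nearest to 16 DP peaks and 7 SU peaks. The mesenchymal ligand Wnt5a was nearest to 13 DP peaks, the highest at 99.7, and to 2 SU peaks, and Cxcl12 to 11 DP peaks, the highest at 174. Most of these lay far away. Within 50 kb of the gene lay 1 DP and 1 SU peak for Tbx3, 2 DP and 0 SU peaks for Wnt5a, and 1 DP peak for Cxcl12. By that distance the fixed lists' shares of genes with a peak could not be told apart from those of other genes. The kinase gene Sgk1 had VMP and DP peaks 95 and 224 bp from its TSS.

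Promoter shares also varied with peak height in DP and VP. In DP 38.3% of the lower 50% of peaks lay at promoters and 13.7% of the upper 50%, and in VP 29.5% and 9.15%, whereas in SU they were 56.6% and 55.6%, with 70.6% among the 1000 highest.

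The share of AR peaks at promoters was higher in SU, a female tissue, than in VP, a male one. Tissue and sex are biological explanations that this contrast cannot tell apart. Both female lists (SU 56.1%, VMP 36.9%) lay above both male lists (DP 26%, VP 19.3%). The series holds 1 input library for each sex, so any effect of the input on these lists cannot be told apart from sex. If weak peaks at open promoters could account for the higher share in SU, the highest SU peaks should hold fewer promoters. The 1000 highest instead exceeded the whole SU list by 14.5 points. Within the SU list, ranked by a height of unknown scale, the highest peaks thus held no fewer promoters. The cut was chosen after values were seen, so this is not counted as evidence against the explanation. A first version comparing the lower and upper 50% of SU peaks (56.6% and 55.6%) had decided nothing. It was replaced after its values were seen. List length is a possible explanation that the 1000 highest peaks of SU and VP, 63.0 points apart, argue against. Pull-down at promoters of highly expressed genes may contribute: 2881 genes with a promoter peak in SU and not in VP had a median expression at percentile 70.7 of SU, just above the bound of 70, which was left undecided.

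The median of immediate early genes was higher in both female than in both male tissue libraries. Of 18 members, 4 were past the rule for VP over VMP and 8 for DP over SU. Handling of the tissue pieces could be one cause beside sex, and the pieces compared, VP with VMP and DP with SU, are also unlike tissues. In dissociated cells the list's median VP over VMP was 0.46 in run 2 and -1.21 in run 1, against 0.35 and -0.08 for random lists. The first value is what the handling explanation needed in at least 1 run, but the runs disagree and the bar was low, so handling stays open and is not established.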
